A study of Mus musculus with 4 samples.

How the data were processed

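RNA of naive CD4+ T cells stimulated with anti-CD3 for 4 hours was sequenced on a BGISEQ-500 platform, per the labels' protocols. The submitters' processing notes name Bowtie2 2.2.5 and the genome build mm10. The quantification tool, the annotation, the read length and the authors' test are not given in the sources used here.

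The only table used holds 16718 genes with their NCBI gene IDs. The FPKM values were deposited as 1 column per genotype, and per the file headers nothing says whether a column is a mean, a sum of reads or a single library. The deposited log2 fold change equals the log2 ratio of the deposited FPKM values, with 0.01 as the lowest value, taken here as 0 (1293 genes in WT and 1095 in cKO). The p-value of each gene is the authors' own, as deposited. The deposited FDR, handled as a score because it reaches 1.03, equals the p-value times the number of genes divided by its rank, apart from the order within ties. Genes marked up or down by the authors are exactly those with a deposited FDR of at most 0.001 and a change of at least 2-fold. The deposited symbols of 24 genes had been turned into dates and were restored by gene ID from a RefSeq table of GRCm38.p6, the assembly that mm10 corresponds to, in which 16685 of the gene IDs were found.

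A gene seen by a single read shows what 1 read is worth in FPKM. Among genes with no read in WT and the p-value of a single read in cKO, FPKM times length (less an offset of 36 bases, fitted) came within 10% of 1 read for 94.3% of 157 genes above 0.05 FPKM. In the opposite direction the share was 87.8% of 147 genes. Reads per gene were estimated from this step, calibrated on the deposited p-values at 56.7 FPKM bases per read, and came to 17365441 for WT and 17208154 for cKO. A negative binomial test of one read number given the other was computed in the manner of Audic and Claverie. Its log10 p-values correlated at r = 0.999 with the deposited ones across 16706 genes, which are not independent replicates. The depth ratio of cKO to WT, 0.991, was also taken from deposited p-values, so part of this agreement was fitted. Within that limit the deposited p-values behave as a test between 2 sets of reads that allows no variation between libraries or animals. The estimated reads were not whole numbers before rounding and were used for intervals and alternatives only.

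Main calls used the deposited FDR below 0.05 among genes with at least 1 FPKM in either genotype, a filter set after the file was seen. The design fixed before the data were examined called for a count model on 4 libraries with gene set tests. It could not be run because the table holds 1 value per genotype, so the unit's fallback scale, log2(FPKM + 1), was used without a test of its own. On this scale the change of genes with low values is understated. A total of 33 gene lists was fixed before the data were examined. For each list with at least 5 genes at 1 FPKM, the median change was placed among the medians of 10000 random lists of the same size, matched on mean FPKM in 20 bins, as a description of these values. Benjamini-Hochberg adjustment of the deposited p-values over the list alone is given beside the calls over all genes.

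Named genes followed a rule fixed beforehand: Zfp281 and Ctla4, the 10 largest changes in each direction among passing genes with at least 5 FPKM in 1 genotype and a symbol that is not a predicted name, and up to 4 passing members of each list with the smallest p-value. The rule's condition that replicate values should not overlap could not be applied, and FPKM replaced CPM. The text names only part of these genes. Ranking list members by p-value favours genes with many reads, so members with larger changes on fewer reads can go unnamed. Cd28, Pdcd1, Btla, Tigit, Foxp3, Ikzf2, Il2, Cd8a, Tbx21 and Cxcr3 were named after their values were seen. So were Ikzf4, Gpr83, Izumo1r, Gm19705, Cxcr4, Rgs1, Rgs2 and Thy1 in the closing section, and the members of gene families first named there.

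The recomputed test and the list percentiles were tested on simulated data. With 200 of 10728 genes changed, the test recovered 50% of 1.2-fold, 82% of 1.5-fold, 90% of 2-fold and 98% of 4-fold changes and called 0.133% of unchanged genes. These reads were drawn with counting error alone, as the test assumes, so the low share of false calls was largely fixed in advance. Recovery with further variation was not computed. When each simulated set of reads varied by a further 10% (CV), 38.8% of unchanged genes were called. Of 200 unshifted random lists, 5.5% fell outside the central 95%, a share that drawing from the same values largely fixes in advance. It does not cover real lists, whose genes may move together and so fall outside more often. Alternatives were another pseudocount, other filters, a size threshold, the region around Zfp281 left out, other scalings and an assumed CV. The assumed CV was put in full on each genotype's set of reads, as if each were a single library. A mean or sum of libraries would carry less of the spread between them. GC content came from the longest GENCODE M21 transcript per gene. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.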

Results

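Naive CD4+ T cells from mice were stimulated through the T cell receptor with an antibody to CD3 for 4 hours, and their RNA was sequenced on a BGISEQ-500 instrument. The labels name 4 libraries, 2 from wild-type cells (WT) and 2 from cells with a conditional knockout of Zfp281 (cKO), a zinc finger transcription factor. The table used here holds 1 expression value per gene and genotype, in FPKM, with no value for a single library. The spread between the libraries of a genotype is therefore unknown, and no difference below has a replicate check. An estimated 17365441 reads stood behind the WT values and 17208154 behind the cKO values, from what a single read is worth in the table. Folds are ratios of cKO to WT values, and their 95% intervals are exact Clopper-Pearson intervals on the estimated reads that cover counting error alone. A gene is said to rise or fall in cKO where its FDR in the authors' deposited table was below 0.05, which compares 2 sets of reads and not 2 conditions.

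The first question was whether the deleted gene was lost. Zfp281 (NCBI gene 226442, GRCm38 chromosome 1, 136624901 to 136630391) had 66.3 FPKM in WT and 0.44 FPKM in cKO, or an estimated 6119 and 40 reads. The cKO value was 0.664% of the WT value (95% interval 0.471% to 0.899%), in the direction that the labels give. The authors' deposited table lists a log2 fold change of -7.23 for Zfp281. The series title names Ctla4, which encodes an inhibitory receptor of T cells, as a gene that Zfp281 represses directly. Ctla4 (NCBI gene 12477, chromosome 1, 60909025 to 60915832) rose from 12.3 FPKM in WT to 28.5 FPKM in cKO, 2.31-fold (95% interval 2.06 to 2.60). Its FDR in the authors' deposited table was 8.96e-48. Cd28 and Icos, which encode costimulatory receptors of the same family and lie on either side of Ctla4, moved the other way. Cd28 fell from 160.3 to 145.8 FPKM, to 0.909 of WT, and Icos from 82.8 to 57.4 FPKM, to 0.692. Neither fall would have passed with a CV of 10% assumed in each genotype's set of reads.

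Ctla4 differed from most other inhibitory receptors. Of the 14 measured members of this list, 3 rose, 7 fell and 4 did not pass. Besides Ctla4, the receptor gene Tigit rose from 7.40 to 13.2 FPKM, 1.78-fold (1.42 to 2.25), and the ubiquitin ligase gene Cblb rose 1.25-fold (1.22 to 1.28). Pdcd1, which encodes PD-1, fell to 0.630 of its WT value (0.578 to 0.686). Btla fell to 0.663 (0.636 to 0.692), Cd274, encoding PD-L1, to 0.657 (0.633 to 0.682), and Vsir, encoding VISTA, to 0.679 (0.664 to 0.694). Cd5 fell from 598 to 447 FPKM. With p-values adjusted over the list alone, 4 members were higher and 8 lower. The list's median change was -0.31 on the log2(FPKM + 1) scale, at percentile 0 of random lists matched on expression, and -0.11 with no filter on low values. With an assumed CV of 10% in each genotype's set of reads Ctla4 alone of this list would have passed, and none of the 7 falls. At an assumed 20% no gene of the list would have passed, Ctla4 included.

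**Figure D1:**
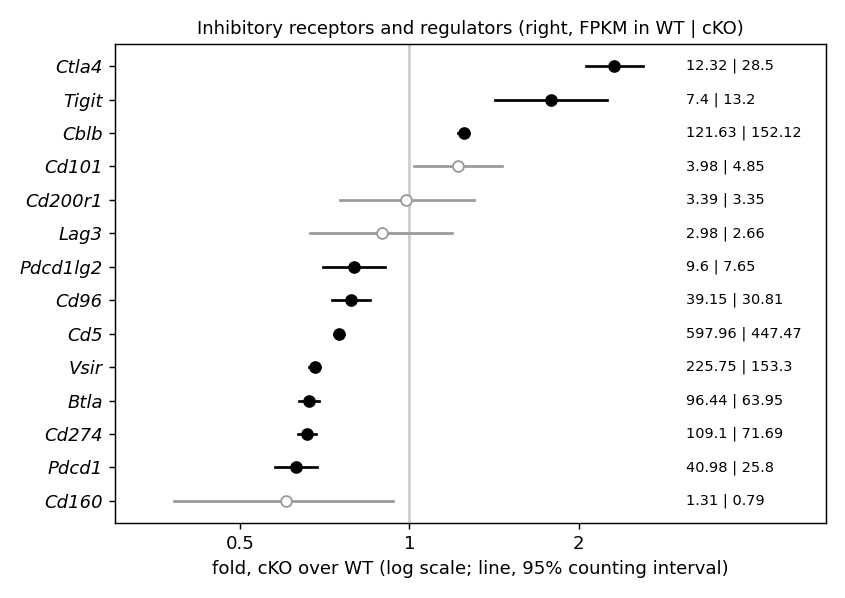
Fold of cKO over WT for the inhibitory receptor list, on a log axis, for members at 1 FPKM or more; lines are 95% counting intervals, filled points passed the deposited FDR threshold, and FPKM values stand at the right. Ctla4 lies at 2.31 and Pdcd1 at 0.630.

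The second question was which other genes differed between the genotypes. Of 10728 genes with at least 1 FPKM in either genotype, 2130 rose and 1811 fell by the FDR in the authors' deposited table. The excess of higher genes depended on the scaling, since a recomputed read test with the median change set to 0 gave 2057 higher and 2150 lower. Most differences were small, with 3409 of these genes under 1.5-fold and 161 at 2-fold or more. The authors marked 157 genes in all, 83 higher and 74 lower, which are the genes with an FDR of at most 0.001 and a change of at least 2-fold in the authors' deposited table. The number of genes called depends on the unknown spread between libraries. By the deposited FDR 3941 genes passed, and the simulation with a 10% CV added to each set of reads called 4083 of 10528 unchanged genes. A count of this size could therefore arise with no change between the genotypes. With an assumed CV of 10% put on each genotype's set of reads, as if each were a single library, 104 genes would have been higher and 83 lower. At 20% 11 would have been higher and 6 lower. If a column joins several libraries, the same CV between libraries would weigh less on it. Counts at 10% stand beside most of the lists below.

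Among passing genes with at least 5 FPKM in either genotype, leaving out predicted genes, the largest rise was in Kif23, which encodes a mitotic kinesin, from 0.97 to 10.5 FPKM, 10.8-fold (8.27 to 14.4). Myo6, an unconventional myosin gene, rose 6.02-fold, and Fanci, a DNA repair gene, rose 3.40-fold. Il12rb2, which encodes a chain of the interleukin-12 receptor, rose from 2.16 to 6.35 FPKM, 2.94-fold (2.35 to 3.72). Epas1, encoding a hypoxia-inducible transcription factor, rose 2.69-fold, the efflux pump gene Abcb1a 2.53-fold, the GTPase gene Gimap7 2.52-fold and the tubulin gene Tubb2b 2.48-fold. Rn7s1 and Rn7s2 had the same values, 2.27 and 8.83 FPKM, and are near-identical copies whose reads cannot be assigned with certainty. On the other side, Slc16a3, which encodes a lactate exporter, fell from 14.8 to 3.30 FPKM, to 0.223 of its WT value (0.184 to 0.268). The phosphatase gene Ppm1j fell to 0.239, the metalloprotease gene Adam19 to 0.337, the glucose transporter gene Slc2a3 to 0.337 and Tnfsf14, encoding the costimulatory ligand LIGHT, to 0.338. Pdlim4 fell to 0.311 and Xkrx to 0.383 of WT. The pseudogene Atp6v0c-ps2 fell to 0.304, and its reads are uncertain because its sequence resembles that of its parent gene. Mir686 fell on an estimated 15 reads in WT and 1 read in cKO.

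Genes of ribosome biogenesis and MYC-linked growth were lower in cKO almost without exception. Of 40 measured members, 39 fell and 1 rose, and the counts adjusted over the list alone were the same. The nucleolar protein gene Ncl fell from 170.7 to 129.7 FPKM, the helicase gene Ddx21 to 0.737 of WT (0.717 to 0.756), and the initiation factor gene Eif4a1 to 0.788 (0.770 to 0.807). The exception was Odc1, encoding the first enzyme of polyamine synthesis, which rose 1.23-fold. The list's median was -0.34 (log2), at percentile 0. Myc itself fell to 0.864 of WT. Of 22 genes of the heat shock and unfolded protein responses, 13 fell and 1 rose, with Hspa8 falling from 1254 to 902 FPKM and Hsp90aa1 to 0.755 of WT. Adjusted over the list alone the counts were again 13 and 1. The changes in these lists were shallow: with an assumed CV of 10% none of the 40 growth genes and none of the 22 heat shock genes would have passed.

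Metabolic genes also fell more often than they rose. Among 28 genes of cholesterol and fatty acid synthesis 16 fell, 3 rose and 9 did not pass, and these counts held when adjusted over the list alone. Idi1 fell to 0.563 of WT (0.511 to 0.619), Cyp51 to 0.582 and fatty acid synthase, Fasn, to 0.757. The median was -0.30 (log2), at percentile 0. Of 24 glycolysis genes 12 fell and 5 rose, over all genes and adjusted over the list alone. Besides Slc16a3 and Slc2a3, Ldha fell from 460 to 361 FPKM and Pkm to 0.809 of WT. The median of the glycolysis list lay at percentile 0.56. At an assumed 10% CV 4 cholesterol and fatty acid genes and 2 glycolysis genes, Slc16a3 and Slc2a3, would have been lower and none higher. Oxidative phosphorylation showed less: 30 of 38 genes did not pass, 7 fell and 1 rose, also when adjusted over the list alone, and the median lay at percentile 11.5.

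Activation markers, cytokine genes and early response genes each held more genes that fell than genes that rose. Of 19 activation markers 11 fell and 6 rose, with Il2rg falling to 0.794 of WT, the transferrin receptor gene Tfrc to 0.713 (0.684 to 0.744) and the amino acid transporter gene Slc7a1 to 0.763. Of 15 cytokine and chemokine genes 8 fell and 3 rose. Tnf fell from 86.5 to 53.1 FPKM, Lta to 0.643 of WT and Tgfb1 to 0.838, whereas Il16 rose 1.36-fold. Il2 was barely detected, at 1.30 FPKM in WT and 0.87 FPKM in cKO, and did not pass. Of 41 genes induced early after receptor engagement 20 fell and 14 rose. The orphan nuclear receptor gene Nr4a1 fell to 0.819 of WT and Egr3 to 0.640, while Tnfaip3, encoding the NF-kappaB inhibitor A20, rose 1.86-fold (1.80 to 1.93) and the kinase gene Pim1 1.54-fold. The counts adjusted over the list alone were the same for these 3 lists. The median lay at percentile 1.1 for activation markers, 1.18 for cytokines and 47.3 for early genes. Few of these calls would have stood at an assumed CV of 10%: 2 activation markers higher and none lower, 2 cytokine genes lower and none higher, and 1 early gene higher and 2 lower.

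Genes of receptor signalling and costimulation moved in both directions. Among 57 T cell receptor signalling genes 28 fell and 18 rose, the same when adjusted over the list alone, with Nfatc1 falling to 0.695 of WT (0.681 to 0.711) and the phosphatase gene Ptprc to 0.842. Of 18 costimulatory receptors and ligands 9 fell and 5 rose, or 10 and 6 adjusted over the list alone. Cd6 fell to 0.711 and Slamf1 to 0.672 of WT. Of 21 exhaustion and anergy genes 10 fell and 7 rose, also adjusted over the list alone, with Ikzf1 falling to 0.776. Their medians lay at percentiles 5.28, 4.76 and 23.9, inside the central 95% of matched random lists. Assuming a CV of 10% would have left 1 signalling gene lower, 2 costimulatory genes higher and 1 lower, and no exhaustion or anergy gene.

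Genes of the naive and quiescent state rose more often than they fell. Of 34 measured, 21 rose, 6 fell and 7 did not pass, or 22 higher and 6 lower adjusted over the list alone. Ccr7, the chemokine receptor that guides naive cells to lymph nodes, rose from 210.4 to 345 FPKM, 1.64-fold (1.59 to 1.69). Txnip, an inhibitor of glucose uptake, rose 1.37-fold, Satb1 1.27-fold and Ets1 1.27-fold. The median was 0.17 (log2), at percentile 100. At an assumed CV of 10% Ccr7 alone of this list would have passed. Among 28 chemokine receptors and adhesion molecules 12 rose and 5 fell, or 13 and 7 adjusted over the list alone. S1pr1, required for exit from lymph nodes, rose 1.34-fold and P2ry10 1.58-fold, whereas the integrin gene Itgb2 fell to 0.775 of WT. Their median lay at percentile 89.7, and the assumed CV would have left 5 higher and 1 lower.

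All interferon-stimulated genes that passed rose. Of 48 measured members 29 rose and 19 did not pass, with 30 higher when adjusted over the list alone. Irf7, a transcription factor that amplifies the interferon response, rose from 21.6 to 35.6 FPKM, 1.65-fold (1.497 to 1.82). Ly6e rose 1.47-fold, Parp14 1.29-fold and the GTPase gene Igtp 1.25-fold. The median was 0.22 (log2), at percentile 100. These rises were small, and with an assumed CV of 10% 1 of the 48 would have passed. Some markers of B cells also rose, at far lower levels. The 5 measured B cell markers at 1 FPKM or more all lay above WT and 2 of them passed, Cd74 (7.63 to 11.9 FPKM) and H2-Aa (1.57 to 3.88 FPKM), or 4 adjusted over the list alone.

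More regulatory T cell genes and T helper lineage factors rose than fell. Of 14 regulatory T cell genes 7 rose, 3 fell and 4 did not pass, or 8 higher and 3 lower adjusted over the list alone. Foxp3, the lineage factor of these cells, was near the lower limit at 0.55 FPKM in WT and 1.26 FPKM in cKO, 2.29-fold (1.54 to 3.50). Tnfrsf18, encoding GITR, rose 1.35-fold, whereas Il2ra, encoding CD25, fell to 0.785 of WT and Tnfrsf9 to 0.755. This list's median was 0.36 (log2), at percentile 100, but 0.01 among genes at 10 FPKM or more. Of 32 T helper factors 14 rose and 10 fell, the same adjusted over the list alone. Ifngr1 rose from 136.3 to 251 FPKM, Il4ra 1.59-fold and Stat5b 1.42-fold. Ikzf1 fell to 0.776 of WT, Tbx21 from 2.32 to 1.36 FPKM and Cxcr3 from 1.87 to 0.58 FPKM. The median of the T helper list lay at percentile 99.96. Of 20 TGF-beta pathway genes 10 rose and 5 fell, also adjusted over the list alone. Tgfbr2 rose 1.19-fold and Tgif1 1.26-fold, whereas Id2 fell to 0.523 and Tgfb1 to 0.838 of WT. The median, 0.13 (log2), lay at percentile 99.0. With no filter on low values it was 0.05 and lay inside the central 95%. Under the assumed CV 3 regulatory T cell genes (Ctla4, Foxp3 and Ikzf2) would have been higher and none lower, 5 T helper factors higher and 2 lower, and 1 TGF-beta pathway gene lower.

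Most proliferation genes did not pass. Of 27 cell cycle genes 21 did not pass, 3 rose and 3 fell, also adjusted over the list alone. Ccnd2, encoding cyclin D2, fell from 139.4 to 77.1 FPKM, 0.553 of WT (0.538 to 0.569), and Pcna to 0.792, while Mcm7 rose 1.24-fold. Of 5 histone genes 2 rose and 3 did not pass. Of 29 p53 target and apoptosis genes 10 rose and 6 fell, or 11 and 6 adjusted over the list alone, with Bcl2 falling to 0.694 of WT. In the list of Zfp281 with its partners and relatives, 3 of 26 genes rose and 7 fell, Zfp281 included, or 3 and 8 adjusted over the list alone. Maz rose 1.31-fold. The medians of these 4 lists lay inside the central 95% of random lists matched on expression. The p53 list lay outside, at percentile 97.7, with length and GC content matched as well, and the cell cycle list lay outside with no filter, at a median of 0.10 (log2). At an assumed CV of 10% 1 gene would have been lower in each of the cell cycle, p53 and Zfp281 partner lists, the last being Zfp281 itself.

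Of 20 memory and effector genes 7 rose and 5 fell, or 9 and 6 adjusted over the list alone, with Id2 falling to 0.523 of WT (0.462 to 0.591). An assumed CV of 10% would have turned that balance, to 1 higher and 3 lower. Of 7 cytotoxic genes 2 rose and 3 fell, Fasl to 0.465 of WT. Some markers of other cells rose in cKO. Of 5 CD8 T cell markers 4 rose, among them Cd8b1, from 11.5 to 17.8 FPKM, and Eomes, from 1.26 to 2.59 FPKM, while Cd8a stood at 0.28 and 0.47 FPKM. Of 8 monocyte, macrophage and dendritic cell markers 3 rose and 1 fell, with Lyz2 at 0.22 and 1.09 FPKM. Of 8 thymocyte markers 4 rose and 1 fell, Cd24a to 0.608 of WT. Both erythroid and platelet markers rose, and Prf1 fell while Eomes rose among the 2 NK cell markers. The neutrophil, mast cell and basophil markers Ms4a2 and Cxcr2 did not pass. The single gamma delta T cell marker above 1 FPKM, Cd163l1, rose from 0.17 to 1.57 FPKM. Adjusted over the list alone the counts of the cytotoxic and cell type lists in this paragraph were the same, except that 1 of the 2 neutrophil, mast cell and basophil markers was higher. Of the lists of other cell types, the medians of the CD8 T cell list (percentile 99.97) and the B cell list (percentile 99.7, or 96.4 with length and GC content matched as well) lay outside the central 95% of lists matched on expression, and those of the monocyte (percentile 76.9) and thymocyte (percentile 85.8) lists inside. Under the assumed CV of 10%, 1 cytotoxic gene would have been lower. Of the markers of other cells 1 of the CD8 T cell, B cell, NK cell, thymocyte and gamma delta T cell lists each and 2 of the monocyte list would have been higher, and none of the erythroid or neutrophil lists. These lists share members. The gene left in the CD8 T cell and NK cell lists was the same, Eomes, and the cytotoxic gene was Fasl, also in the p53 and memory lists. Xist, expressed from the inactive X chromosome of females, stood at 70.7 FPKM in WT and 64.5 FPKM in cKO.

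**Figure D2:**
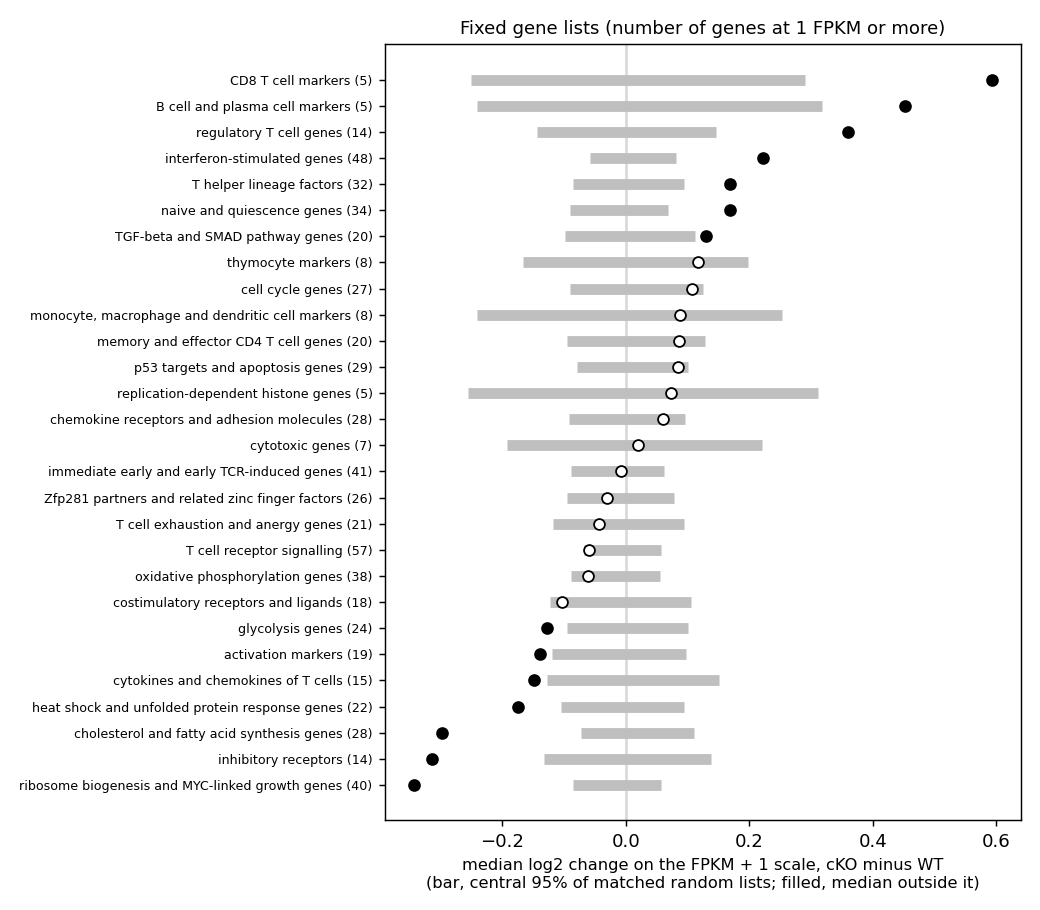
Median change of each fixed gene list, cKO minus WT, on the log2(FPKM + 1) scale, with the number of genes at 1 FPKM or more in brackets; grey bars are the central 95% of 10000 random lists matched on mean expression, and filled points lie outside them. Of 28 lists with at least 5 genes, 7 lie above and 7 below.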

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

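Settings other than the pseudocount of 0.1, no filter, the 2-fold threshold and the region around Zfp281 were chosen after seeing the data. The fall of Zfp281, -5.55 on the log2(FPKM + 1) scale, was -6.94 with a pseudocount of 0.1 and -7.23 with none, as a smaller pseudocount must give for a value near 0. The rise of Ctla4 stayed between 1.13 and 1.21 (log2). A change of at least 2-fold left 87 genes higher and 74 lower, and the authors' own mark at 1 FPKM or more left 63 and 60, by construction. The other filters and scalings kept both counts within 1.5 times of 2130 and 1811. The share of higher calls was 54.0%, and 48.9% when the median change was set to 0. An assumed CV of 10% on each genotype's set of reads left 104 genes higher and 83 lower. One of 20% left 11 and 6, because it widens the error of every gene. Ctla4 had an adjusted p of 1.7e-05 at 10% and 0.698 at 20% (z test with Benjamini-Hochberg adjustment). Of 128 named genes that passed, 44 passed at 10% and 8 at 20%. Of 28 lists, 14 lay outside the central 95% of random lists, and all 14 stayed outside with a pseudocount of 0.1. Random lists do not keep any tendency of a list's genes to move together, which alone could put lists outside. With no filter 32 lists could be tested and 13 of the 14 stayed, without the TGF-beta list, while the cell cycle, memory and effector, and neutrophil lists were added. At 10 FPKM or more 23 lists could be tested. Of the 14 the CD8 T cell and B cell lists had too few genes, 11 stayed and the regulatory T cell list moved inside, while the chemokine receptor list was added. With length and GC content matched as well 13 stayed, without the B cell list, and the p53 list was added. No paired analysis was possible because the table gives no value per replicate. For the same reason leaving out a replicate, the replicate block, the other normalizations, count models and gene set tests were not run.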

Other observations

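Some gene families defined by symbol had most of their passing members on one side. They were picked after looking over 609 gene ontology terms and 19 families defined by symbol, so their counts describe these values and test nothing. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, 17 fell and none rose, with Iars at 0.740 of its WT value and Eprs at 0.761. All 8 subunits of the CCT chaperonin, which folds actin and tubulin, fell, Tcp1 to 0.778 and Cct3 to 0.796 of WT. Of 38 proteasome subunits 16 fell, none rose and 22 did not pass. Mitochondrial ribosomal protein genes fell in 14 and rose in 1 of 74, with 59 not passing, whereas cytosolic ribosomal protein genes rose in 34 and fell in 6 of 76, with 36 not passing and a median change of 0.04 (log2).

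Of 8 GIMAP GTPases, which are expressed in resting lymphocytes, 7 rose and none fell, with Gimap3 rising from 725 to 1023 FPKM. Guanylate-binding protein genes, some of which are also in the interferon-stimulated list, rose in 8 of 10. MHC genes, among them H2-Aa of the B cell list, rose in 12 of 22 and fell in 1, with H2-Ob rising from 14.98 to 30.8 FPKM and H2-Q8 from 60.0 to 92.5 FPKM. Septin genes fell in 4 of 6, Septin11 to 0.569 of WT. Kif23 rose 10.8-fold although 21 of 27 cell cycle genes did not pass.

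Of the tests below, those on GC content, T cell share, cell samples, regulatory T cells and flanking DNA were chosen after the result was seen. The ribosome biogenesis list was lower in cKO, with a median of -0.34 (log2). Against bias by GC content or transcript length, the median lay at percentile 0 of random lists matched on expression, length and GC content. A lower share of T cells in the cKO sample would lower T cell genes as much. But 12 such genes had a median of -0.055 (log2, quartiles -0.15 and 0.10), although 6 of them fell and 3 rose. Thy1 fell to 0.507 of WT. A difference between the cell samples unrelated to genotype, such as slower activation in one culture, cannot be told apart from an effect of Zfp281, because the table gives 1 value per genotype. An effect of Zfp281 on growth after stimulation therefore remains a hypothesis.

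The rise of Ctla4 may come from a larger share of regulatory T cells, which express Ctla4 at rest, although the labels call the cells naive and a selection for naive cells would remove most of them. Foxp3 rose 2.29-fold on an estimated 36 and 82 reads, and its interval of 1.54 to 3.50 holds the 2.31-fold rise of Ctla4. The ratio of Ctla4 to Foxp3 was 22.4 in WT and 22.6 in cKO, with the same counting error. That it hardly differed only restates the folds of both genes. Its level bears on whether regulatory T cells gave most of the Ctla4 reads, but no value from such cells was at hand. Equal folds would point to a larger share only if regulatory T cells gave most of the Ctla4 reads, which these values cannot show. Of the 13 regulatory T cell genes besides Ctla4, only Foxp3 and Ikzf2 (1.99-fold, 1.61 to 2.46) had intervals that reached the fold of Ctla4, and the other 11 lay below it, among them Ikzf4 at 1.67-fold, Izumo1r at 1.01-fold and Gpr83 at 0.809-fold, but activated conventional T cells express several of these. Beside them 4 of 5 CD8 T cell markers and 2 of 5 B cell markers rose. At an assumed CV of 10% 1 of each was left, Eomes and H2-Aa. Cd8a did not pass, at 0.28 FPKM in WT and 0.47 FPKM in cKO. The cytotoxic list lay at percentile 52.2, and the monocyte and thymocyte lists at percentiles 76.9 and 85.8. Release from repression by Zfp281, which the series title names, was not tested here and stays open beside a larger share of regulatory T cells.

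Within 10 Mb of Zfp281, 4 of 69 other genes at 1 FPKM or more carried the authors' mark, all higher in cKO, while by the deposited FDR 17 of the 69 rose, 15 fell and 37 did not pass. They were Gm19705, 53.005 kb from Zfp281, which rose from 8.16 to 43.7 FPKM, and Cxcr4, Rgs1 and Rgs2, which lie 7.37 to 8.04 Mb away and rose 2.04-fold to 2.31-fold. Chance clustering gave as many marked genes in 4.27% of windows around 10709 other genes, just under the limit of 5% set beforehand. These windows overlap and were not matched on their number of genes. Of 144 separate bins of 20 Mb, 2 held as many (1.39%, exact 95% interval 0.169% to 4.93%). So narrow a margin does not exclude chance. DNA flanking the targeted allele could raise these 4 genes, but only if it differs between WT and cKO, which was not known here. The loss of Zfp281 itself could also raise them, and without sequence of the region these explanations cannot be told apart.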
